A study of Mus musculus with 2 samples.

How the data were processed

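ChIP-seq for H3K4me2 was done on stomachs of B6NCrl mouse embryos at embryonic day 16.5, in 2 biological replicates. Per the labels, each was a pool of stomachs of both sexes, with fragments of 300 to 500 bp, and replicate 1 joins 2 technical replicates. The deposited files are peak lists in narrowPeak format on mm10, per the text description deposited with the files: 1 list per replicate, 1 list called on the pooled reads of both, and 1 list of replicated peaks derived from the other 3. Each replicate was called against a different control alignment, per the same description, so a difference between the replicates can come from their controls. The peak caller, its version, its threshold, the aligner and the rule for a replicated peak are not given in the sources used here. Control alignments, reads and coverage tracks were not used here.

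The signal value of each peak is the authors' enrichment over control as deposited, a linear value that was not rescaled between lists. The −log10 p and −log10 q values are those the authors deposited for each peak. The smallest −log10 p was 2.01 in both replicate lists, and q was over 0.05 for 6.51% of the peaks of replicate 1 and 2.05% of those of replicate 2. All 41060 replicated peaks are unchanged entries of the pooled list, so their widths and signal values come from the pooled reads, and the replicate lists give the error. Of the replicated peaks, 36990 touched a peak in both replicate lists, 926 in replicate 1 alone, 3019 in replicate 2 alone and 125 in neither. With no read counts the depth is unknown, and a promoter without a peak was below the calling threshold, which does not show that the mark was absent.

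Start sites, exons and gene spans came from GENCODE M21 on GRCm38, with 55413 genes and 132721 start sites on 21 chromosomes, and sequence from the GRCm38 reference. A gene was called marked when a peak overlapped the 1 kb on either side of any of its start sites by at least 1 bp. Peaks were joined across gaps of up to 500 bp into domains, and a gene's domain length is the bases covered by peaks in the longest domain over a start site. Distal peaks lay over 1 kb from any start site and were counted within 50 kb of the gene's most upstream start. Each peak was placed by its midpoint as promoter, exon, intron or intergenic, in that order. Chance levels came from 100 shuffles of the peaks within chromosomes, and from 20 shuffles where alternatives to the promoter share were computed. Promoter CpG content is the observed to expected ratio in the 1 kb centred on the most upstream start site. A gene can be marked at another start site, so its CpG quintile need not be that of the marked promoter. CpG-matched shares were tested with a Mantel-Haenszel test over quintiles.

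The gene lists, the consensus sequences, the tests, most alternatives and the rule for named genes were fixed before the data were examined. The 19 fixed lists held 419 names, of which 418 were in the annotation. The absent name, Cblif, is the newer symbol of Gif, which was listed too. Sfrp1 is on both the mesenchyme list and the morphogen list. Hox genes and olfactory receptors, taken by symbol, made 21 lists. Several lists are not private to their cell type: Hand2 and Kit, for example, are known in other cells of the gut, and bulk tissue does not assign a peak to a cell type.

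Marked shares were tested with Fisher's exact test against all other protein-coding genes, two-sided. Domain lengths and distal counts were tested by the place of the list median among medians of 10000 random lists of the same size. The lists of each replicate were compared with an exact McNemar test. Consensus sequences were counted on both strands in the 500 bp around each distal peak's midpoint and in windows 5 kb to either side that touch no peak. A Mantel-Haenszel odds ratio over 10 GC strata compared the counts, and 10 shuffled letter orders per sequence gave a further background. P-values were adjusted by Benjamini-Hochberg over the 21 lists or over the sequences with a value, with 0.05 as the threshold. They are across genes or windows, which are not independent replicates, and hold for these libraries. All samples form 1 group, so no test between conditions was possible.

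Genes are named by a fixed rule. It takes up to 4 members of each list that were marked in both replicates and had the longest domains, and the unmarked members of a list where at most 5 were unmarked. It also takes the 10 longest domains, the 5 highest promoter signal values, the 5 genes with most distal peaks, all Hox genes, and 5 fixed-list genes marked in 1 replicate alone. Genes named only as members of a wholly marked list (such as Barx1 or Shh) illustrate that list.

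Alternatives were each replicate list alone, the pooled list, and q under 0.001. Promoter windows of 500 bp and 2 kb, the most upstream start alone, an overlap of at least 500 bp and a 50% reciprocal overlap were also tried, as were the 20000 strongest peaks. Others were other joining distances, distances of 20 and 100 kb, 200 bp windows, flanks at 20 kb, and backgrounds matched on CpG content or on being marked. Random lists matched on peak strength and on the number of start sites were added after seeing the data.

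The tests were tested on simulated data. Among 20000 simulated genes, 17 of 20 lists marked at 98% against 70%, and 18 of 20 marked at 30% against 70%, were recovered, and 0 of 160 unchanged lists were called. Doubled domain lengths were recovered in 10 of 20 lists and tripled ones in 17 of 20, with 0 of 120 false calls. The McNemar test recovered its 1 planted list, which was marked fully in 1 of the simulated replicates. The other 199 lists were identical in both simulated replicates, so their 0 calls were fixed in advance and give no false-call rate. Among 4000 windows of evenly drawn random bases, a sequence planted in 5% of them was recovered and 0 of 2 others were called. Sites as rare as those of GRHL (0.338% of distal peaks) and differences in GC content were not simulated. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, pysam 0.24.0, samtools 1.23.1 and matplotlib 3.10.9 were used.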

Results

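The data describe H3K4me2 (histone H3 dimethylated at lysine 4) by ChIP-seq in the mouse stomach at embryonic day 16.5, in the strain B6NCrl. H3K4me2 is known at promoters and at distal regulatory elements. The samples form 1 group of 2 biological replicates, each a pool of stomachs from embryos of both sexes, and the pool of replicate 2 came from 41 embryos, per the labels. No other tissue, age or condition was measured, so genes are compared with other genes of the same libraries. The files hold peak lists without read counts, so the depth of either library is unknown. Peaks that the authors kept as replicated lead below, and the spread comes from the list of each replicate, as mean ± SD (n = 2). Coordinates are 1-based on mm10 (GRCm38).

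The first question was how much of the genome carried the mark. The strongest promoter peaks lay at Dnm1, with a signal value of 66.5 in the replicated list and 51.6 ± 5.14 in the replicates, at Abhd3 (60.3, replicates 47.0 ± 4.54) and at Prss12 (58.3, replicates 47.9 ± 7.13). Ppil6 and Smpd2 shared a peak with a signal value of 57.5 (replicates 46.6 ± 3.39). Dnm1 encodes dynamin 1, and its longest marked domain on chromosome 2 from 32317032 to 32320359 lay 92.9% in introns, within 1 kb of an annotated internal start site. The longest domain and the highest signal value of a gene were taken separately over all its start sites. The strongest Dnm1 peak therefore need not lie in this domain. Signal values are those of the authors' peak caller, and at these 5 genes the replicated list, which carries the values of the pooled reads, had higher ones than either replicate. The replicate lists held 55910.5 ± 1290 peaks with a median width of 507 ± 21.2 bp, and covered 47.2 ± 2.55 Mb, or 1.73% ± 0.0936 of the genome. The replicated list held 41060 peaks with a median width of 922 bp, covering 51.2 Mb or 1.88%. The authors' pooled list held 61077 peaks with a median width of 544 bp.

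The next question was how far the replicates shared their regions. Of the peaks of replicate 1, 79.6% touched a peak of replicate 2, and 73.2% of the peaks of replicate 2 touched 1 of replicate 1. After shuffling peaks within chromosomes the share was 3.88%, with a highest value of 4.14% in 100 shuffles. Promoter peaks of the replicated list were in both replicate lists in 96.9% of cases, against 85.0% of intergenic, 81.2% of intronic and 87.4% of exonic peaks. In the pooled list, which was not selected for replication, these shares were 84.6%, 50.2%, 41.8% and 54.8%. Unshared peaks were weak and narrow: their median signal value was 3.23 in replicate 1 and 3.55 in replicate 2, against 8.30 and 10.7 for shared peaks, and their median width was 213 and 233 bp against 702 and 812 bp. Covered bases shared by both lists made up 71.5% of the bases covered by either. Across 43785 shared peaks the signal values correlated with a Spearman rho of 0.776, a correlation across peaks, which are not independent replicates.

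**Figure D1:**
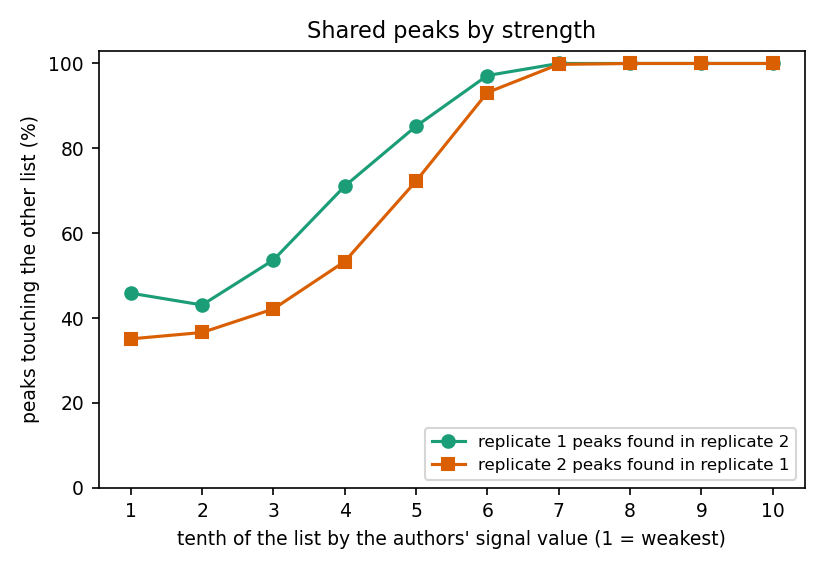
Percent of each replicate's peaks that touch a peak of the other replicate (y axis), for 10 groups of equal size in each list ordered by the authors' signal value from weakest to strongest (x axis). The share was 45.9% for replicate 1 and 35.1% for replicate 2 in the weakest group, and 100% for both in the strongest group.

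The position of the peaks was compared with shuffled positions. Promoters, within 1 kb of an annotated start site, held 50.2% of the replicated peaks and 44.3% ± 1.49 of the replicates' peaks, against 6.38% of shuffled peaks, a ratio of 7.87. Exons held 4.38% (ratio 1.29), introns 26.2% (ratio 0.650) and intergenic sequence 19.3% (ratio 0.385). Promoter peaks had a median width of 1391 bp and a median signal value of 21.6, against 618 bp and 4.96 in introns and 621.5 bp and 5.70 in intergenic sequence. Exonic peaks were 739.5 bp wide at the median with a signal value of 6.98. The promoter share rests on the peak list and on the window: it was 38.7% in the pooled list and 35.1% with a 500 bp window.

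The next comparison was which promoters were marked. Nr2f2, Gata4, Foxf1, Ptch1, Zeb2, Col1a1 and every housekeeping gene on the list, such as Gapdh and Polr2a, were marked in both replicates. Phox2b, Plp1 and Vip were marked in neither, although they serve as markers of enteric neurons or glia. Of 21911 protein-coding genes, 15066 (68.8%; replicates 69.2% ± 0.287) had a replicated peak within 1 kb of a start site. Both replicates marked 14960 genes, replicate 1 alone 156 and replicate 2 alone 245, and 6550 were in neither. Genes in 1 replicate list alone were mostly weak, with a median signal value of 3.45 in replicate 1 and 3.75 in replicate 2, against 19.9 and 23.7 for genes marked in both. Among fixed-list genes, Rbpjl, Tlx2, Krt13 and Nppb were marked in replicate 2 alone and Tie1 in replicate 1 alone. Rbpjl was not weak, with a signal value of 21.2 in replicate 2. At that strength 100% of replicate 2 peaks touched a replicate 1 peak. At Rbpjl the replicate 1 peak thus lay outside the 1 kb window, and the region was not private to replicate 2. Marking followed promoter CpG content closely: 12.9%, 43.9%, 89.3%, 98.4% and 99.4% of genes were marked from the lowest to the highest quintile of CpG observed to expected ratio. On the X chromosome 52.3% of 948 genes were marked, against 70.1% of autosomal genes.

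The marking of 21 gene lists was then compared. Every gene of the gastric patterning transcription factors (30 of 30, among them Barx1, Sox2, Gata4 and Nkx3-2), the simple epithelium (25 of 25, with Cdh1, Krt8 and Elf3), smooth muscle (22 of 22, with Acta2 and Myh11), mesenchyme (24 of 24, with Col1a1 and Pdgfra), morphogen signalling (40 of 40, with Shh and Ptch1) and housekeeping (20 of 20) was marked in both replicates. Gland products of the mature stomach were marked at 12 of 27 genes (44.4%; replicates 46.3% ± 7.86), including Muc1, Cym, Cldn18 and Slc26a9. Olfactory receptor genes, a background of genes used mainly in the nose, were marked at 6 of 1134 (0.529% in each replicate). Germline genes were marked at 3 of 20, namely Dazl, Dppa3 and Adam2.

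By Fisher's exact test (two-sided, Benjamini-Hochberg over 21 lists, across genes), 8 lists were marked above other protein-coding genes. The adjusted p was 0.000145 for the gastric patterning transcription factors, 0.000497 for simple epithelium, 0.00102 for smooth muscle, 0.000704 for mesenchyme, 4.24e-06 for morphogen signalling and 0.00204 for housekeeping. Hox genes were marked at 34 of 39 (adjusted p 0.0229), and brain regional transcription factors, such as Pax6 and Neurog2, at 20 of 22 (adjusted p 0.0313). Only simple epithelium (adjusted p 0.0136), smooth muscle (0.00252), mesenchyme (0.00258) and morphogen signalling (0.0314) stayed above genes of the same promoter CpG quintile (Mantel-Haenszel test). There the gastric patterning factors had an adjusted p of 0.106 against a matched share of 88.9%, housekeeping 0.254 and brain factors 0.992, and Hox genes turned to the other side, with 87.2% against 89.5%. The gastric and housekeeping lists were wholly marked, so no higher share was possible. Against matched shares of 88.9% and 89.9%, the matched test could not have called lists of their size above. CpG content was taken at the most upstream start site, which need not be the marked one. The brain call was lost in every other setting but q under 0.001: in replicate 2 alone (adjusted p 0.0603), replicate 1 alone (0.0520), the pooled list (0.0521), windows of 500 bp (0.0918) or 2 kb (0.0516) and the most upstream start alone (0.147).

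Marked below other genes were gland products (adjusted p 0.0192), blood and immune cells (10 of 24, 0.0132), intestine (8 of 19, 0.0313), liver (6 of 19, 0.00204), pancreas (6 of 20, 0.00109), germline (7.12e-06) and olfactory receptors. With CpG matching, germline (15% against 60.1%, adjusted p 4.31e-05) and olfactory receptors (0.529% against 21.2%) stayed below. Gland products (44.4% against 38.9%) and blood (41.7% against 37.7%) then lay above matched genes, both with no call. Intestine, liver and pancreas kept their side without a call (adjusted p 0.907, 0.846 and 0.123). In replicate 2 alone the gland products (51.9%, adjusted p 0.0827), blood (50%, 0.0698) and intestine (47.4%, 0.0698) had no call, and in replicate 1 alone blood (50%, 0.0915) and intestine (47.4%, 0.0683) had none. In the pooled list gland products (55.6%, adjusted p 0.171) and blood (58.3%, 0.307) had none, nor had intestine with 2 kb windows (0.0633) or the most upstream start alone (0.0765).

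No call was made for 6 lists. The squamous forestomach epithelium was marked at 11 of 20 genes (adjusted p 0.250), at 70% in replicate 2 and at 45% in replicate 1, where the list was called below other genes (adjusted p 0.0452), with Grhl3, Pkp1, Krt15 and Perp having the longest domains. Skeletal and cardiac muscle was marked at 11 of 20 (0.250), enteric neurons and glia at 20 of 24 (0.227; called above in the pooled list, 0.0376), endothelium at 17 of 24 and mesothelium at 7 of 10 (both 1). Interstitial cells of Cajal, the pacemaker cells of the gut, had all 8 genes marked, among them Kit and Etv1 (exact adjusted p 0.0839). No higher share was possible with 8 genes, so Fisher's test could not have called this list above. The unmarked enteric genes were Phox2b, Plp1, S100b and Vip, and S100b had a peak in replicate 2 alone. The unmarked mesothelial genes were Gpm6a, with a peak in replicate 1 alone, Upk3b, with a peak in replicate 2 alone, and Muc16. The unmarked brain genes were Neurod6 and Otx2.

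**Figure D2:**
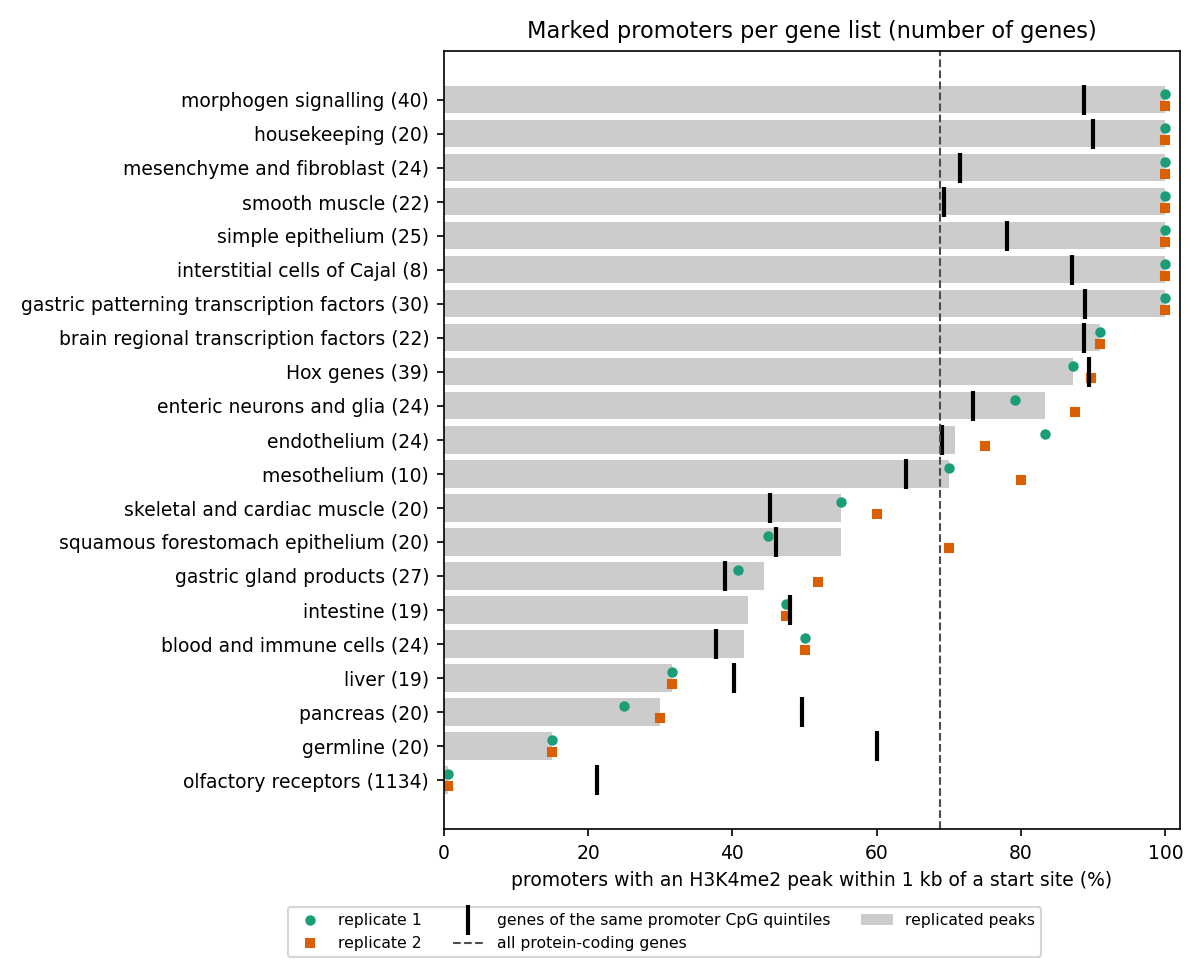
Percent of the genes of each list with an H3K4me2 peak within 1 kb of a start site (x axis), for the replicated peaks (bars) and each replicate (points), with the number of genes in parentheses, the share of genes of the same promoter CpG quintiles (ticks) and that of all protein-coding genes (dashed line, 68.8%). The bars run from 0.529% for olfactory receptors to 100% for 7 lists.

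The length of the marked domain over a promoter separated the lists further. Nr2f2, which encodes a transcription factor of the gut mesenchyme, had a domain of 25731 bp on chromosome 7 between 70344718 and 70371321 (replicates 25009.5 ± 29.0), 46.7% of it exonic and 28.9% intronic. Ptch1, the hedgehog receptor, had 24507 bp on chromosome 13 between 63549120 and 63574044 (replicates 21438.5 ± 2659), with 89.3% of that span in introns. Foxf1, another mesenchymal factor, had 18889 bp on chromosome 8 between 121072407 and 121091696 (replicates 16025.5 ± 3598), 83.6% of it intronic in the annotation. Exon and intron shares count every annotated gene, and Foxf1 itself spans only 121084386 to 121088144, so most of this domain lies outside Foxf1. Gata4 had 18270 bp on chromosome 14 between 63236526 and 63256580, but 9234.5 ± 2529 in the replicates. Meis1 had 15772 bp (replicates 15315 ± 508). The median over all marked genes was 2310 bp, with a middle range from 1710 to 3125 bp, and 62 genes lay above 10000 bp. Domain lengths of single genes correlated between the replicates with a Spearman rho of 0.915, a value across genes.

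The gastric patterning factors had a median of 7896 bp (replicates 7274 ± 385), against 2311 bp in random lists of marked genes. Morphogen signalling genes followed with 5605 bp (replicates 5220.5 ± 326), led by Ptch1, Fgfr2 (11323 bp), Smad7 (9846 bp) and Hes1 (8808 bp). Smooth muscle genes had 4745 bp (replicates 3898 ± 885), led by Tpm1 (10280 bp), Flna (7901 bp), Csrp1 (7086 bp, but 4498 bp in replicate 1) and Tpm2 (6740 bp). Mesenchymal genes had 3993 bp (replicates 3912 ± 202), led by Zeb2 (15203 bp), Col1a1 (10195 bp), Pdgfra (9587 bp) and Col5a1 (6521 bp). Simple epithelial genes had 3782 bp (replicates 3320.5 ± 55.9), led by Prss8 (7379 bp, but 4334 bp in replicate 1), Elf3 (6653 bp), Krt19 (6248 bp) and Ehf (6193 bp). Housekeeping genes had 3647 bp (replicates 3440 ± 60.8), led by Polr2a (5303 bp), Tbp (5002 bp), Tubb5 (4939 bp) and Gapdh (4483 bp).

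In 10000 random lists of the same size, no list median reached those of these 6 lists, so each had the smallest p the draws allow (0.0002, adjusted 0.000467, two-sided). Hox genes had a median of 2988 bp (adjusted p 0.0110), but 2757 bp in replicate 1 and 1854 bp in replicate 2, where the median fell below that of random lists (adjusted p 0.152), so this call rests on replicate 1. It was lost in the pooled list too (2519 bp, adjusted p 0.445). Neighbouring Hox genes also share domains, such as 62064 bp counted for each of Hoxb2 to Hoxb6 and 22658 bp for Hoxa3, Hoxa5, Hoxa6 and Hoxa7. Random lists draw genes singly, so the Hox p counts a shared domain more than once and overstates the evidence. These 7 lists kept their calls against random lists matched on promoter CpG content and on peak strength, the latter chosen after seeing the data. For Hox genes neither matching takes account of the shared domains.

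Shorter domains were called for 10 lists. Squamous forestomach genes had a median of 737 bp (replicates 654 ± 59.8, adjusted p 0.000467), although Grhl3 had 6184 bp (replicates 5363.5 ± 639) and Perp 3206 bp (3290 ± 525). Pkp1 had 3746 bp but 1604.5 ± 1404 in the replicates, with 612 bp in replicate 1, and Krt15 3496 bp but 2209.5 ± 493, with 1861 bp in replicate 2. Skeletal and cardiac muscle genes had 930 bp (replicates 596.5 ± 13.4, adjusted p 0.000467), with Actn3 at 2369 bp. Blood and immune genes had 1175 bp (replicates 907 ± 32.2, adjusted p 0.00252), with Runx1 at 7994 bp and Ikzf1 at 2270 bp. These 3 lists stayed below random lists matched on peak strength (adjusted p 0.0210, 0.0449 and 0.00105). When peaks were joined across 2 kb, the squamous genes (1964 bp, adjusted p 0.251) and the blood genes (2075 bp, 0.372) lost their call, and the blood genes lost it with CpG matching too (0.0837).

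The other shorter lists lost their call against lists of the same peak strength. Gland products had a median of 1536.5 bp (adjusted p 0.0139, then 0.612), but 897 bp in replicate 1 and 1188 bp in replicate 2. Muc1 had 7716 bp (replicates 6777.5 ± 657) and Slc26a9 3099 bp (2324 ± 337), while Cym had 3596 bp but 682 bp in replicate 1 (1986 ± 1844) and Cldn18 3422 bp but 1236 bp in replicate 1 (2400.5 ± 1647). Intestinal genes had 1232.5 bp (0.00665, then 0.283), with 821 and 990 bp in the replicates. Satb2 among them had 4198 bp (replicates 4035.5 ± 108) and Vil1 1412 bp (938.5 ± 302). Liver genes had 1226 bp (replicates 1084 ± 15.9; 0.0114, then 0.390), with Apoh at 3225 bp (2992.5 ± 354). Pancreas genes had 1391.5 bp (replicates 1223 ± 198; 0.0319, then 0.389), with Nkx6-1 at 3942 bp (3205.5 ± 770). Brain factors had 1558.5 bp (replicates 1426 ± 24.4; 0.00382, then 0.162), with Pax6 at 2944 bp (2348 ± 141). Germline genes had 709 bp (replicates 646.5 ± 94.0; 0.0123, then 0.241). Olfactory receptors had 756.5 bp (0.000467, then 0.05001), but 389.5 and 480 bp in the replicates. Gland products (0.341), intestine (0.0690) and liver (0.170) had no call with CpG matching either. The pancreas call was also lost in replicate 2 alone (1363.5 bp, adjusted p 0.0684), with no joining of peaks (0.167), with joining across 2 kb (0.171) and with start-site matching (0.0868). Intestine lost its call in the pooled list (1600 bp, 0.0748) and with joining across 2 kb (1659 bp, 0.0729), and brain factors with no joining (0.136) and across 2 kb (0.0562).

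No call on length was made for 4 lists. Interstitial cell genes had a median of 3172.5 bp (replicates 2857 ± 185; adjusted p 0.0939, and 0.0314 with no joining of peaks), led by Kit (4974 bp; replicates 4163.5 ± 1306), Etv1 (4813 bp; 5226 ± 631), Gja1 (3635 bp; 3699 ± 369) and Cd34 (3364 bp; 2749 ± 96.2). Enteric genes had 1893 bp (replicates 1746.5 ± 30.4; adjusted p 0.0945), although Hand2 had 12251 bp (11364.5 ± 999) and Erbb3 5162 bp (4565 ± 320). Ednrb had 7166 bp but 2665 and 4368 bp in the replicates, and Gfra1 6224 bp but 4170 ± 154. Endothelial genes had 2102 bp (adjusted p 0.458), but 1388.5 bp in replicate 1 alone, where they were called shorter (adjusted p 0.00540), and 1873 bp in replicate 2. Among them Fli1 had 6141 bp (replicates 4435.5 ± 885), Eng 3583 bp (3202 ± 194) and Egfl7 3351 bp but 1607 ± 123 in the replicates. Mesothelial genes had 1498 bp (adjusted p 0.0520), and 1294 bp in replicate 2 alone, where they were called shorter (0.0247), with Tbx18 at 2349 bp (2104.5 ± 189) and Rspo1 at 2320 bp (1779 ± 192).

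**Figure D3:**
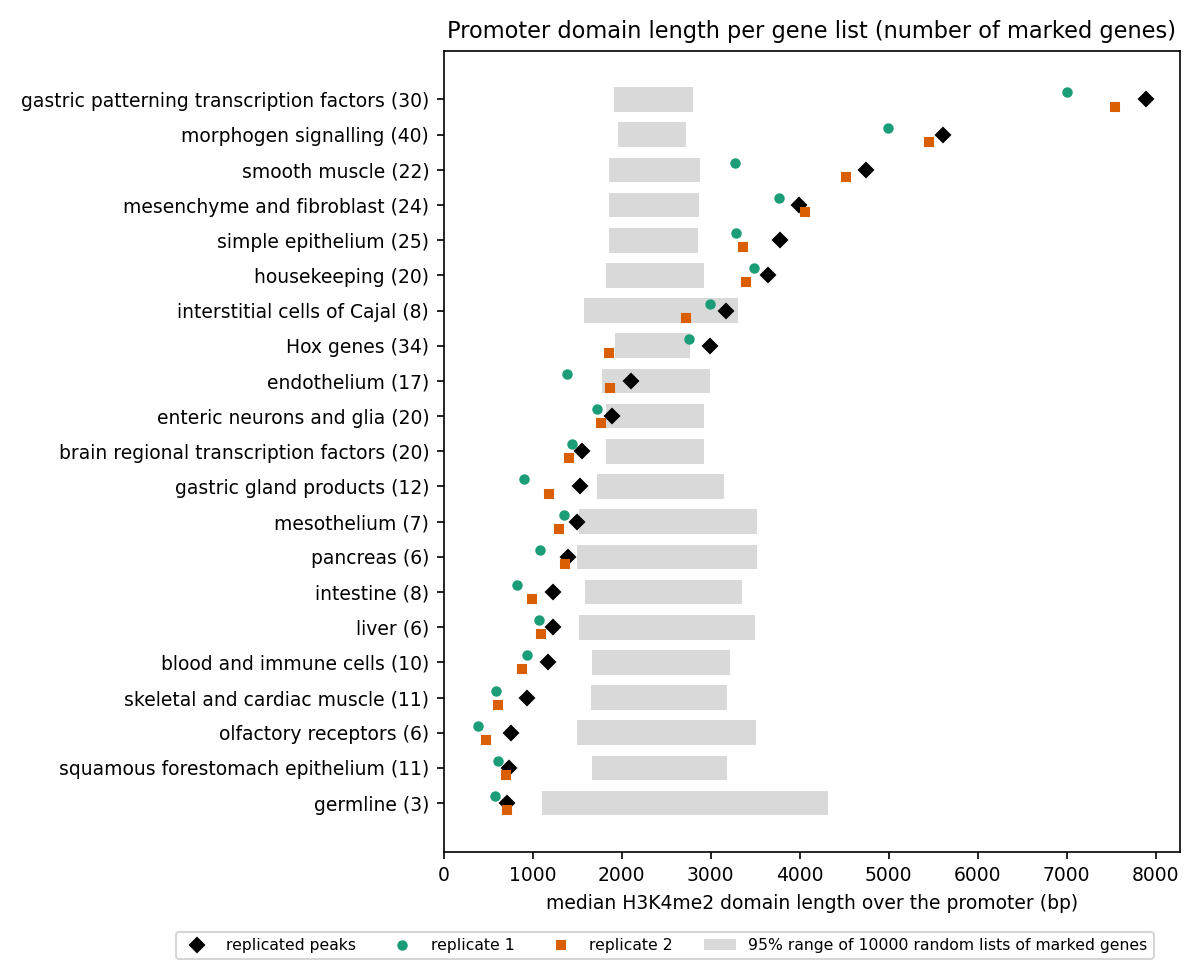
Median length in bp of the H3K4me2 domain over the promoters of each list's marked genes (x axis), for the replicated peaks (diamonds) and each replicate (points), beside the 95% range of 10000 random lists of the same size (grey bars). The gastric patterning transcription factors lie at 7896 bp against a range of 1911 to 2800 bp, and the squamous forestomach genes at 737 bp against 1668 to 3188 bp.

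Distal peaks around the genes were counted next. Gata4 had the most of all protein-coding genes, with 17 replicated peaks over 1 kb from any start site and within 50 kb of its most upstream start (replicates 28 ± 4.24). Hist1h2bh and Hist1h3f followed with 15 each, Hist1h3g with 14, and Btn1a1 was among 8 genes tied at 13. On chromosome 13, the most upstream starts of these named genes lie between 23465901 (Btn1a1) and 23544052 (Hist1h3f). The 50 kb around them thus overlap, and the same distal peaks can count for more than 1 of them. Among other named genes, Hes1 had 10 (12 and 16 in replicates 1 and 2) and Smad7 9 (14 and 14). Ehf also had 9 (6 and 14), and Foxf1 had 7 (11 and 7). Of all protein-coding genes, 48.6% had none. The median per gene was 4 for simple epithelium (replicates 5.5 ± 0.707), 3.5 for gastric patterning factors (6.5 ± 0.707), 3 for morphogen signalling (3.5 ± 0.707) and 3 for Hox genes (7.5 ± 0.707), against 0.5 to 1 in random lists. These 4 lists shared an adjusted p of 0.00105 from 10000 random lists, the smallest possible here, and kept it against random lists of marked genes. Neighbouring Hox genes count the same distal peaks, such as 7 at each of Hoxb3 to Hoxb6. Random lists draw genes singly, so the Hox p treats shared peaks as separate and overstates the evidence. Within 20 kb the Hox median was 1 and the call was lost (adjusted p 0.0588). The replicate lists, which hold more and narrower peaks, counted more distal peaks for Gata4 and for these 4 lists, except that morphogen signalling had 3 in replicate 1 as well.

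Smooth muscle, mesenchyme, endothelium, brain factors and housekeeping genes had a median of 2 distal peaks and did not pass the threshold (adjusted p 0.0588 for each). Against random lists of marked genes the adjusted p was 0.501 for endothelium and 0.315 for the other 4, while at q under 0.001 all 5 passed (0.0438 to 0.0467). Mesenchyme passed it in replicate 2 alone (adjusted p 0.00240) and in replicate 1 alone (0.0371), endothelium in replicate 2 alone (0.00240), and smooth muscle (0.0408) and housekeeping (0.0499) in replicate 1 alone. In the pooled list mesenchyme (0.0108), endothelium (0.00700) and housekeeping (0.0331) passed, within 100 kb mesenchyme (0.0246) and endothelium (0.0105), and within 20 kb mesenchyme (0.00140). Mesenchyme thus passed in every setting but the replicated list within 50 kb and the lists of marked genes. Interstitial cell genes also had 2 (adjusted p 0.253). Gland products, squamous, enteric, blood, mesothelium, pancreas, skeletal and cardiac muscle and germline genes had a median of 1, and intestine, liver and olfactory receptor genes had 0. In replicates 1 and 2 the medians were 2 and 2 for gland products and for skeletal and cardiac muscle. They were 1.5 and 2.5 for squamous genes, 2 and 1 for enteric genes, and from 1 to 1.5 for blood, mesothelium, pancreas and germline. Intestine had 1 and 0, liver 0 and 1, and olfactory receptors 0 in both. Squamous genes had 3.5 in the pooled list (adjusted p 0.0310), and olfactory receptors were below random lists in replicate 2 alone (adjusted p 0.000840), in replicate 1 alone (0.00105), in the pooled list (0.000840) and within 100 kb (0.00105). With the replicated peaks within 50 kb none of these lists passed the threshold (adjusted p 0.598 for olfactory receptors and unadjusted p of 0.873 or more for the others).

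Consensus sequences of transcription factors were then searched in 18324 distal peaks and in 29849 flanking windows 5 kb away, with GC content held in 10 strata. FOX sites (TGTTTAC) were in 9.83% of distal peaks and 6.51% of flanks, with an odds ratio of 2.10 (95% interval 1.956 to 2.26; replicates 1.89 ± 0.0641). GRHL sites (AACCGGTT), bound by grainyhead factors of epithelia, had an odds ratio of 2.74 (1.73 to 4.34; replicates 3.15 ± 0.304). MEF2 sites of muscle had 2.41 (1.97 to 2.93; replicates 1.94 ± 0.0883), and RUNX sites had 1.20 (1.10 to 1.31; replicates 1.12 ± 0.0246). GRHL sites were in 0.338% of peaks and 0.104% of flanks and MEF2 sites in 1.27% and 0.807%, but RUNX sites were in 5.48% of peaks and slightly more of the flanks, so their excess appeared only within GC strata. The odds ratios of these 4 lay above those of all 10 letter-shuffled versions of their sequence. Against flanks their adjusted p was 4.37e-91, 6.75e-06, 1.08e-17 and 7.44e-05 (Mantel-Haenszel test). Only for FOX did the whole 95% interval lie above the highest shuffled value (1.30). The lower bounds of GRHL, MEF2 and RUNX lay under their highest shuffled values of 2.07, 2.02 and 1.11. Over 200 bp windows GRHL (1.45, adjusted p 0.372) and RUNX (1.07, 0.372) lost their call, and RUNX did so too with flanks at 20 kb (1.09, 0.0504).

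CTCF sites (CCASYAGRKGGC) were in 2.93% of distal peaks against 0.372% of flanks, with an odds ratio of 6.80 (5.47 to 8.45; replicates 5.23 ± 0.304; adjusted p 9.11e-92). NFI sites had 4.75 (2.27 to 9.97; replicates 4.19 ± 0.520; adjusted p 3.34e-05) and HNF1 sites 3.32 (1.57 to 7.02; replicates 5.21 ± 1.87; adjusted p 0.00144), at 0.169% and 0.0928% of distal peaks. Single shuffled versions of these 3 were too rare for a comparison, and NR2F sites were too rare for any value. Another 9 sequences passed the threshold but lay within the range of their shuffled versions: GATA (1.21), AP-1 (1.08), TEAD (1.13), SOX (1.35), ETS (2.25), MEIS (1.06), E-box (1.42), KLF (1.23) and CDX (1.24). Of these, KLF did not pass in replicate 1 alone (1.06, adjusted p 0.479) or in 200 bp windows (1.24, 0.128), and MEIS did not in 200 bp windows (1.05, 0.103) or with flanks at 20 kb (1.04, 0.0683). GATA (6.66% of peaks, 6.75% of flanks) and CDX (3.23%, 3.41%) were less frequent in peaks than in flanks, so their excess appeared only within GC strata. No call was made for SRF (1.13, adjusted p 0.0587), HNF4 (1.20, 0.123), NKX2 (1.05, 0.554), BARX (1.05, 0.670) and p53 (0.956, 0.415). SRF passed the threshold in replicate 2 alone (1.17, adjusted p 0.00184), in replicate 1 alone (1.19, 0.00101), in the pooled list (1.17, 0.000516) and with flanks at 20 kb (1.29, 0.000166), HNF4 in replicate 2 alone (1.20, 0.0344) and in the pooled list (1.22, 0.0141), and p53 with flanks at 20 kb (0.892, 0.0286). BARX turned to 0.849 in the pooled list (adjusted p 0.0324). NKX2 and p53 took values on either side of 1 across settings, without a call save for p53 with flanks at 20 kb.

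**Figure D4:**
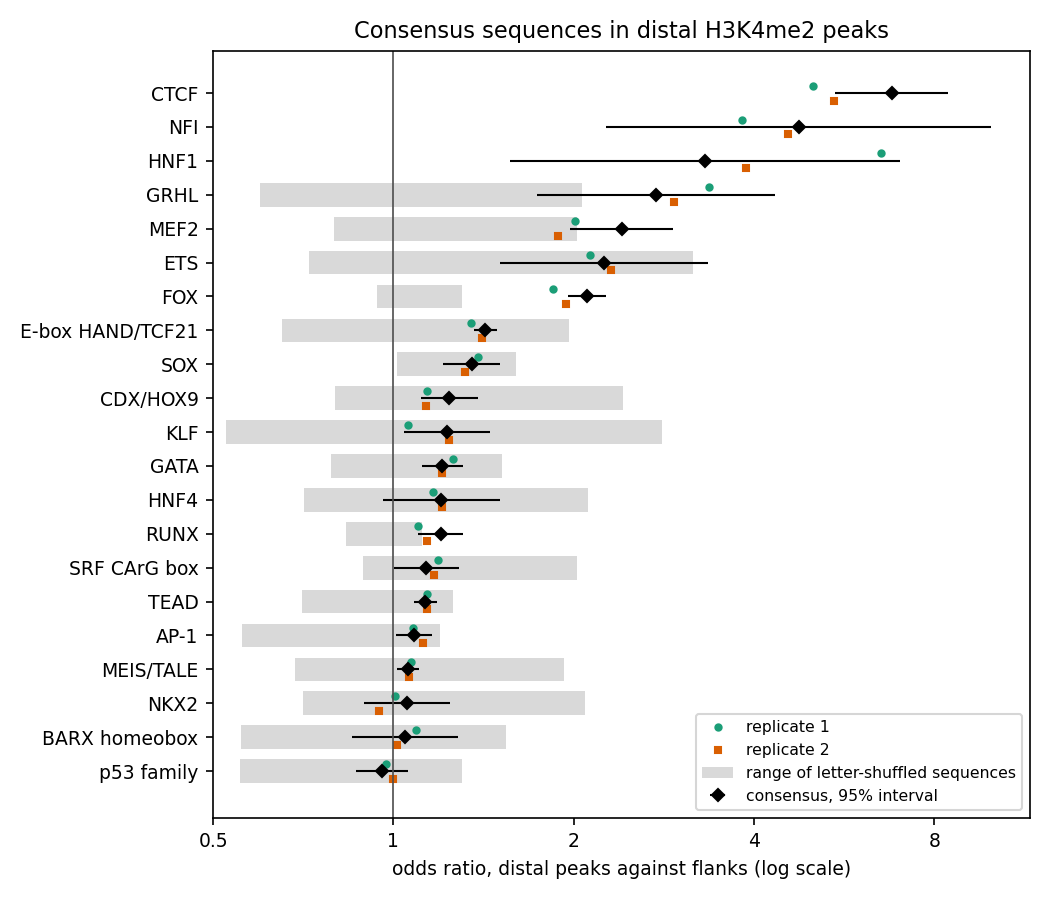
Odds ratio of each consensus sequence in distal peaks against flanking windows (x axis, log scale), with its 95% interval (diamonds), each replicate (points) and the range of letter-shuffled versions (grey bars, absent where the shuffled sequences were too rare). CTCF lies highest at 6.80, and FOX at 2.10 lies above its shuffled range of 0.940 to 1.30.

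The Hox clusters, which carry a code of position along the gut, were described gene by gene. Hoxb2 to Hoxb6 lay under 1 domain covering 62064 bp on chromosome 11 between 96291613 and 96355449, 51.8% of it intronic, the longest of all protein-coding genes. In the replicates, the domain over Hoxb3 to Hoxb6 covered 39466 ± 10364 bp and that over Hoxb2 5662.5 ± 1671 bp. Hoxa1 and Hoxa2, with the neighbouring gene 5730596B20Rik, lay under 25257 bp on chromosome 6 between 52156662 and 52181976 (replicates 26062 ± 2326), and Hoxa3, Hoxa5, Hoxa6 and Hoxa7 under 22658 bp. In the replicates the longest domain was 18311 ± 202 bp at Hoxa5 and Hoxa6. At Hoxa7 it was 18454 bp in replicate 1 but 3160 bp in replicate 2. At Hoxa3 it was 18454 bp in replicate 1 but 27707 bp in replicate 2, the length given for Hoxa1 and Hoxa2 in replicate 2. The Hoxa3 start codon (52172647) lies within the span of the 25257 bp domain. The 2 replicate values of Hoxa3 are thus not lengths of the same domain. Hoxc4 had 8814 bp, and in the D cluster Hoxd8 had the longest domain at 2039 bp. The unmarked genes were Hoxa11, Hoxc11, Hoxc12, Hoxd10 and Hoxd12, and Hoxd10 had a weak peak in replicate 2 alone. The posterior genes Hoxb13 (292 bp), Hoxa10 (355 bp) and Hoxc10 (396 bp) had short domains, while Hoxa13 had 1463 bp and a signal value of 19.6. Long transcripts that start far from a gene's coding part can lend it a distant domain, so peak cover was also taken in the 4 kb around each start codon. There the median was 94.98% for paralogs 1 to 5 (replicates 90.6% and 92.7%), 77.7% for paralogs 6 to 8 (78.7% and 72.9%) and 16.0% for paralogs 9 to 13 (12.4% and 16.8%). Hoxd3 (0%), Hoxd4 (23.6%), Hoxd1 (39.0%) and Hoxb1 (37.6%) were exceptions among paralogs 1 to 5, no higher than the 46% of Hoxa9.

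**Figure D5:**
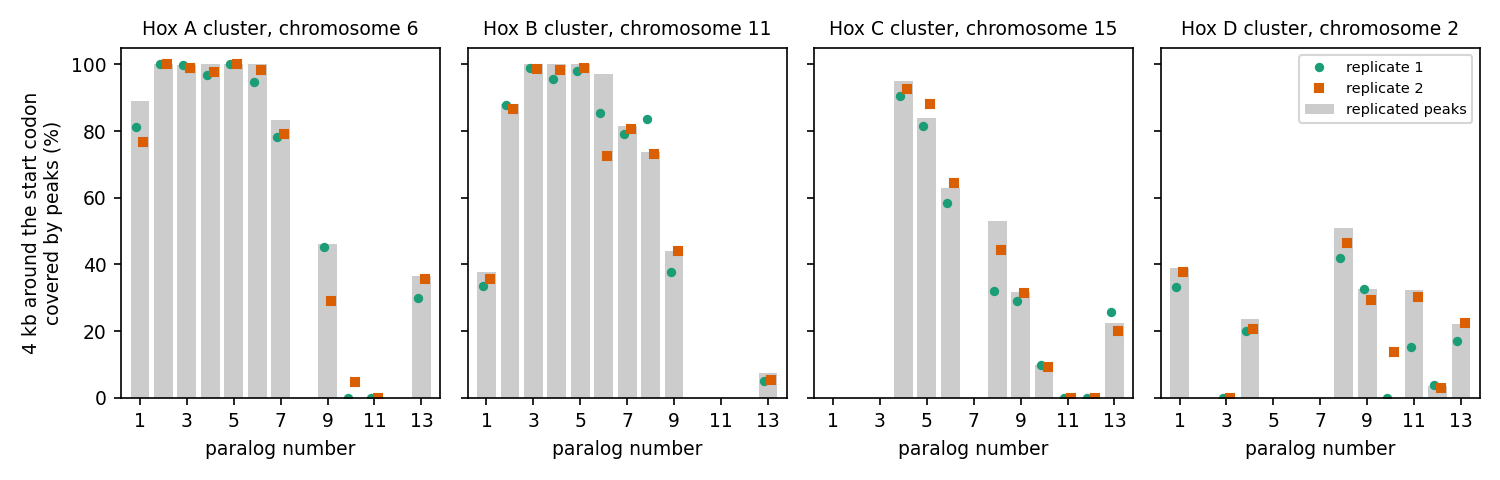
Percent of the 4 kb around the start codon covered by peaks (y axis) for each Hox gene by paralog number (x axis), in the A, B, C and D clusters, for the replicated peaks (bars) and each replicate (points). Cover had a median of 94.98% for paralogs 1 to 5 and 16.0% for paralogs 9 to 13.

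The last comparison set replicate 1 against replicate 2 per list, for a difference in tissue makeup between the pools. Squamous forestomach genes were marked in replicate 2 alone at 6 genes, among them Krt13, and in replicate 1 alone at 1 (exact McNemar p 0.125). Gland products had 3 genes in replicate 2 alone and none in replicate 1 alone (exact p 0.250), and endothelial genes had 3 in replicate 1 alone, among them Tie1, and 1 in replicate 2 alone (exact p 0.625). Blood genes had 3 on either side. Over all fixed lists 29 genes were in 1 replicate alone, 9 in replicate 1 and 20 in replicate 2. No list had an unadjusted exact p under 0.05. With peaks of q under 0.001 alone, the squamous genes stood at 6 against 0 (exact p 0.0313, adjusted p 0.656). No list had more than 7 genes in 1 replicate alone, and the smallest adjusted p that such counts allow over 21 lists is 0.328, so the exact McNemar test could not have called any list. The McNemar test thus says nothing on whether the pools differ. At promoters marked in both replicates, the log2 ratio of signal values was also compared with random lists of the same size. No list passed, and gland products had the lowest p (median 0.555, random-list p 0.0310, adjusted p 0.651).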

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

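Peaks outside the main comparisons above were listed once the lists had been read. Unplaced scaffolds held 14 replicated peaks. They are counted in peak number, width, cover and replicate overlap. No comparison by gene or position used them, since those were kept to the chromosomes. All 14 touched peaks of both replicates, with a median signal value of 7.31 (3.21 to 14.6). The pooled list held 20017 peaks that the authors did not keep as replicated. Their median signal value was 3.002 and their median width 234 bp, and 15.2% lay at promoters. Of these, 4750 touched a peak of replicate 1 alone, 8097 of replicate 2 alone, 165 of both and 7005 of neither. In all, 7130 pooled peaks touched no peak of either replicate list, of which 125 were among the replicated peaks. The 20017 pooled peaks not kept as replicated entered the values given for the pooled list and the choice of flanks free of peaks. They were not counted in the comparisons of replicated peaks. No explanation was tested for any of the peaks listed here.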

How the results depend on the processing

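The backgrounds matched on peak strength and on start-site number were chosen after the data were seen. No paired analysis was possible because the samples form 1 group. Peak number was 54998 to 56823 in single replicates and 61077 in the pooled list, median width 492 to 522 bp and 544 bp, and cover 45.4 to 49.0 Mb and 56.5 Mb. The mean share of replicate peaks in the other list was 82.8% at q under 0.001, 58.2% with 50% reciprocal overlap and 93.1% for the 20000 strongest peaks, and shared bases were 75.05% (q under 0.001) and 78.7% (strongest peaks). Promoters held 43.2% to 45.3% of peaks in single replicates, 38.7% in the pooled list, 35.1% with 500 bp windows and 58.9% with 2 kb, or 6.79 to 7.13, 6.10, 10.2 and 5.09 times the shuffled share, since a wider window also takes more shuffled peaks. Marked protein-coding promoters were 69.0% to 69.4%, 70.1%, 68.1% and 69.6% in the same order, 65.2% from the most upstream start alone and 66.9% with 500 bp of overlap.

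With CpG matching, lists marked above fell from 8 to 4 and those below from 7 to 2, and in single replicates 4 to 6 lists were below. Gland products (44.4%), blood (41.7%) and Hox genes (87.2%) then turned to the other side of their background without a call. The gastric patterning and housekeeping lists lost their calls as their background rose from 68.7% of other genes to 88.9% and 89.9% of CpG-matched genes. Both were wholly marked, and at their size no call was possible against such a background. The matched test thus does not decide whether they exceed genes of like CpG content. Shorter domains fell from 10 lists to 5 when peaks were joined across 2 kb, to 6 with CpG matching and to 3 with peak-strength matching. The Hox median was 1854 to 2757 bp in single replicates, and at 1854 bp, without replicate 1, it turned below random lists. Lists with more distal peaks rose from 4 to 8 in the pooled list, 9 at q under 0.001 and 6 to 7 in single replicates. Lists with fewer rose from 0 to 1 in the pooled list, 1 within 100 kb and 1 in each single replicate. Sequences above all shuffles rose from 4 to 7 in the pooled list and 7 in each single replicate, and fell to 2 in 200 bp windows. BARX turned to 0.849 in the pooled list. The cause of these changes was not tested.

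Of the results for single lists, 135 on marking, 161 on length and 123 on distal peaks neither turned their direction nor crossed the threshold, as did 101 for single sequences. Without a turn, calls were lost in 21, 22, 1 and 7 and gained in 2, 3, 21 and 7. The direction turned in 10, 3, 2 and 7. Of these, 3 on marking and 1 on length lost a call, BARX gained one, and the others had no call in either setting.

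Among those without a call, squamous genes turned above other genes in replicate 2 alone (45% to 70% in single replicates, with a call below at 45%), in the pooled list (80%) and with CpG matching (55%), as did skeletal and cardiac muscle genes with CpG matching (55%). Endothelium turned below other genes at q under 0.001 (66.7%) and from the most upstream start alone (62.5%), and mesothelium with 500 bp windows (60%). The endothelial length turned above random lists with no joining of peaks (2102 bp) and with joining across 2 kb (2803 bp). Within 100 kb enteric genes (median 1 distal peak) turned below random lists and intestine (2) above. NKX2 had 0.945 to 1.01 in single replicates, 0.974 in the pooled list, 0.895 in 200 bp windows and 0.998 with flanks at 20 kb. For p53 sites the values were 0.973 to 1.00 in single replicates and 1.03 in the pooled list. The cause was not tested.

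The exact McNemar test held too few genes to call any list, at q under 0.001 and with 500 bp or 2 kb windows too, so it gives no measure of stability. No value could be given for NR2F sites in any setting, or for HNF1 and NFI sites in 200 bp windows and with flanks at 20 kb, since a value needs the site in at least 10 peaks and 10 flanks. Flanks with the site numbered 6 and 3 in 200 bp windows and 9 and 9 at 20 kb. Depth is unknown, so it is open how many weak promoters were missed.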

Other observations

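Gene families and gene types were chosen after the data were seen. So were the tests of CpG content and of joined peaks for the gastric factors and the test of the order of Hox genes, while the other tests below were written before their result was seen. Meis and Pbx genes, which encode partners of Hox proteins, were all marked (7 of 7) and had a median domain of 8162 bp, with 5290 and 7495 bp in the replicates, against 2150 bp in random lists of the same promoter CpG content (adjusted p 0.0008 over the families, the smallest possible). Meis1 is also on the gastric patterning list. Histone genes of the replication-dependent clusters had 3396 bp (3402 and 3128 bp in the replicates) against 2638 bp in CpG-matched lists (adjusted p 0.0008), with 60 of 67 marked, below the 97.3% of matched genes (adjusted p 3.54e-05). Neighbouring histone genes can share a domain, as Hist1h2bh and Hist1h3f did (2296 bp), so the p for length counts shared domains more than once. Zinc finger genes named Zfp were marked at 319 of 365, above the 80.5% of CpG-matched genes (adjusted p 0.000114), yet their domains were shorter at 1974 bp (1830 bp in both replicates) than the matched 2227 bp (adjusted p 0.0008). Collagens were marked at 40 of 44, above the 70.3% of matched genes by a Mantel-Haenszel test (adjusted p 0.00135), and ribosomal protein genes at 72 of 72 (adjusted p 0.0162). Sox and Wnt genes were marked at 19 of 19 each and Fox genes at 39 of 44, with no call after CpG matching (adjusted p 0.357, 0.0972 and 0.949).

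Clustered protocadherins were marked at 15 of 56 genes, against 80.7% of genes of like CpG content, with a median domain of 734 bp. Keratins were marked at 17 of 53, against 52.8% of matched genes (adjusted p 0.00291). Vomeronasal receptors were marked at 1 of 326, keratin-associated proteins at 0 of 57, beta-defensins at 0 of 42 and bitter taste receptors at 0 of 35. Cytochrome P450 genes of the Cyp2 family were marked at 9 of 48 and Ly6 genes at 5 of 17, with no call after matching (adjusted p 0.357 and 0.674). Claudins were marked at 15 of 23, Tbx genes at 11 of 13, Irx genes at 6 of 6 and Fgf genes at 19 of 22, with no call. Of other gene types, 56.6% of processed transcripts, 40.4% of antisense genes, 20.2% of lincRNA genes and 17.3% of microRNA genes had a peak at a start site, against 2.69% of processed pseudogenes and 0 of 218 immunoglobulin variable segments.

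The long domains of the gastric patterning factors were tested against 4 technical explanations, and the tables argue against each as the whole cause. The list median of 7895.5 bp lay above the 95% range of random lists matched on promoter CpG content (1938 to 2802 bp), on start-site number (1802 to 2712 bp) and on peak strength (1776 to 2625.5 bp). With no joining of peaks the median of 5242 bp still lay above its range of 1550.5 to 2329 bp. The design gives no other group, so no biological explanation was tested.

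CTCF sites were in 536 distal peaks, which were narrower (median 414 against 595 bp), had a higher signal value (6.69 against 5.01) and were in both replicates more often (86.0% against 81.6%) than the other distal peaks. Weak peaks do not account for them: the site was in 1.20%, 2.10%, 3.86% and 4.54% of peaks over 4 groups from weakest to strongest, an odds ratio of 3.91 (2.89 to 5.28) between the outer groups. Nor does base composition, since 50 shuffled letter orders pooled gave an odds ratio of 1.25 (1.12 to 1.40), below the lower bound of 5.47 for the site itself. Promoters missing from the annotation stay open: the CpG ratio was 0.396 with the site and 0.349 without, a difference of 0.0467 (permutation p 1e-05, the smallest that 100000 permutations can give). No biological explanation was tested, and CTCF binding was not measured here.

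Cover of Hox genes fell with paralog number across 39 genes (Spearman rho -0.654; permutation p 2e-05 within clusters), a value across genes that are neighbours and not independent. The fall rests on paralogs 9 to 13: without them rho was -0.0652 across 23 genes (permutation p 0.679), and without any other paralog group or cluster it stayed between -0.562 and -0.780. Rho was -0.737 in cluster A, -0.423 in B, -0.895 in C and -0.285 in D. The CpG ratio at the most upstream start site did not account for the fall, since that ratio rose with paralog number (rho 0.225). The partial rho was -0.645 (permutation p 3e-05). For some genes that site lies far from the start codon, as at Hoxd3 (74711927 against 74744012). CpG content around the start codon, where cover was taken, was not tested. In cluster D the low-numbered genes had little cover too, from 0% at Hoxd3 to 39.0% at Hoxd1. No biological explanation was tested.

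For the squamous genes marked in replicate 2 alone, a generally stronger enrichment in replicate 2 and more squamous epithelium in its pool cannot be told apart. The 7 and 8 genes tested are too few. The different controls and the unknown depth of the replicates stay open too, and were not tested. The share in replicate 2 alone was 85.7% of 7 genes, against 60.7% of the other genes in 1 replicate alone (239 in replicate 2 and 155 in replicate 1; exact binomial p 0.257, smallest possible 0.0474), and the log2 ratio of signal values at 8 genes marked in both was 0.41, within -0.05 to 0.56 of random lists. The short domains of brain factors (1558.5 bp) lay inside the range of lists of the same peak strength (1476 to 2550 bp), so weaker peaks are a candidate explanation for them.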
